A study of Mus musculus with 12 samples.

How the data were processed

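RNA from ileal mucosal scrapings of 4 groups (wild type or POR-null, control or quercetin diet) was hybridised to Affymetrix 430A arrays, 3 arrays per group, each a pool of 3 mice. The authors deposited log2 expression values, 1 per probe set and array. The submitters' processing notes name MAS5 and RMA, with neither a role nor a version for either. The values ran from 2.66 to 14.04 with nearly equal array medians and no negatives, and were used as deposited, without another normalization. The number of arrays limited the precision.

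Of 22690 probe sets, 64 array controls were left out and 22626 were tested. The platform annotation gave 1 symbol to 20380 of them, several to 691 and none to 1555; of the first, 20351 were matched by gene ID to the gene table of assembly GRCm38.p6, used for names only, and 29 were not. A gene with several probe sets was represented by the one with the highest mean over all 12 arrays. No tested probe set carried the symbol Por, so the targeted gene is not analysed here and the genotype labels were not checked against it.

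A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 5.59 prior degrees of freedom). The median residual SD was 0.109 on the log2 scale. The median SE was 0.0886 for differences between a pair of groups, 0.125 for the interaction and 0.0627 for the averages. Contrasts were the quercetin effect in each genotype, the genotype effect on each diet, their interaction and both average effects. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 over 39 lists fixed before the data were examined (835 listed names, 700 measured, 674 genes of which 26 were on more than 1 list), adjusted over the lists of a contrast. Beside it camera ran with a correlation estimated from the arrays, and fry (statmod 1.5.0). None of the calls made at the preset correlation held with the estimated one, or by fry.

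Genes were named by a rule fixed before the data were examined. Where fewer than 10 genes passed in a contrast, which held for every contrast, the 5 with the smallest p in each direction are given as values, or the 10 with the smallest p for the interaction, leaving out predicted genes without a gene name. Of each list described, up to 4 members with the smallest p are named.

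On simulated data with known changes in the wild-type quercetin contrast (10 simulations over 22626 probe sets, 50 changed per size, independent noise), the test called 80.4% of changes of 0.5 on the log2 scale, 99.4% of changes of 1, 100% of 1.5 and 99.8% of 2, each with the right sign, and 5.57% of its calls were wrong. These shares hold for 200 changed probe sets per simulation. With fewer changed ones the adjusted threshold is harder to reach, so they are not the power on the real arrays. There, differences of 0.81 (Cd79b) and 0.77 (Hnrnpd) in that contrast did not pass. In the unchanged contrast the test made 1 call over all simulations. A list shifted by 0.3 was called in 10 of 10 simulations and 0 of 380 unshifted lists were called; the noise there had no correlation between genes.

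The alternatives tried were quantile normalization, centring each array on its median, leaving out the dimmest probe sets (below the lower quartile of their mean levels) or all below the median level, eBayes with trend and robust, array weights, the replicate number as a block, only the arrays compared, the mean of all probe sets of a gene, other thresholds, and leaving out each array in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.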

Results

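Gene expression was measured in mucosal scrapings of the ileum, the last part of the small intestine, from male wild-type mice and from mice null for cytochrome P450 reductase (POR). POR passes electrons to the microsomal P450 enzymes. After 14 days on a soya-free powdered diet, mice received the same diet alone (control) or with the flavonol quercetin at 6.2 g per kg, given as 7 mg per mouse, and tissue was taken after 24 h. The 12 arrays formed 4 groups of 3, and each array held RNA pooled from 3 mice. Values were log2 expression levels of 22626 probe sets, of which 20380 carried 1 gene symbol and stood for 12393 genes. Array medians lay between 5.91 and 5.96. Pairs of arrays within a group correlated across probe sets with r between 0.9917 and 0.9956, and pairs from different groups with r between 0.9897 and 0.9954. The first principal component held 19.89% of the variance, and wild-type control replicate 2 lay at -19.50 on it while the other 11 arrays lay between -7.38 and 7.08. That array also had the highest score for genes of the proximal small intestine, 0.55 against -0.29 to 0.13 in the others (log2 units, mean of the genes after centring each). The score of 19 smooth muscle and stroma genes was -0.27 ± 0.22 on control and -0.19 ± 0.38 on quercetin in wild type, and 0.22 ± 0.56 and 0.23 ± 0.17 in POR-null (SD, n = 3). On the control diet this difference was smaller than the SD of the POR-null group. Por itself is not analysed here, and the labels do not say in which tissues the reductase was deleted.

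The first comparison asked which ileal genes responded to quercetin in wild-type mice. Gas5, a long non-coding RNA gene whose introns hold small nucleolar RNAs, rose from 7.61 ± 0.20 to 8.78 ± 0.06 (log2 level, SD, n = 3), and all 3 quercetin arrays lay above all 3 control arrays. The difference was 1.18 ± 0.12 (log2, SE), or 2.26-fold (limma, adjusted p = 0.00293). In POR-null mice Gas5 was at 8.46 on control and 8.48 on quercetin, so wild-type control was the lowest of the 4 groups. The difference alone does not show whether the wild-type quercetin or the wild-type control pools departed from the rest. The 3 other probe sets of Gas5 differed by 0.41 to 0.93 and did not pass (adjusted p from 0.0577 to 0.266), and the mean of all 4 differed by 0.81 (adjusted p = 0.0561). The next smallest p-values belonged to genes that did not pass. Among those higher on quercetin were Cd79b, a signalling chain of the B cell receptor (0.81 ± 0.13), the RNA-binding protein gene Hnrnpd (0.77 ± 0.12), both at an adjusted p of 0.0577, and Bcl7b (0.41 ± 0.07). Among those lower were Gda, guanine deaminase (-0.68 ± 0.10), Deptor, an inhibitor of mTOR signalling (-0.62 ± 0.12), Ehd2 (-0.33 ± 0.06) and the secreted protein gene Fam3b (-0.41 ± 0.08). Without wild-type control replicate 1, Hnrnpd and Gda passed (limma adjusted p = 0.0411 for each), as did Hnrnpd without POR-null control replicate 1 (0.0488) and Gda without POR-null control replicate 3 (0.00428). Leaving out wild-type control replicate 1 kept as wild-type controls replicate 2, which lay apart, and replicate 3, next lowest on the first component (-7.38). Genes that passed only in that setting, here and below, rest on those controls.

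**Figure D1:**
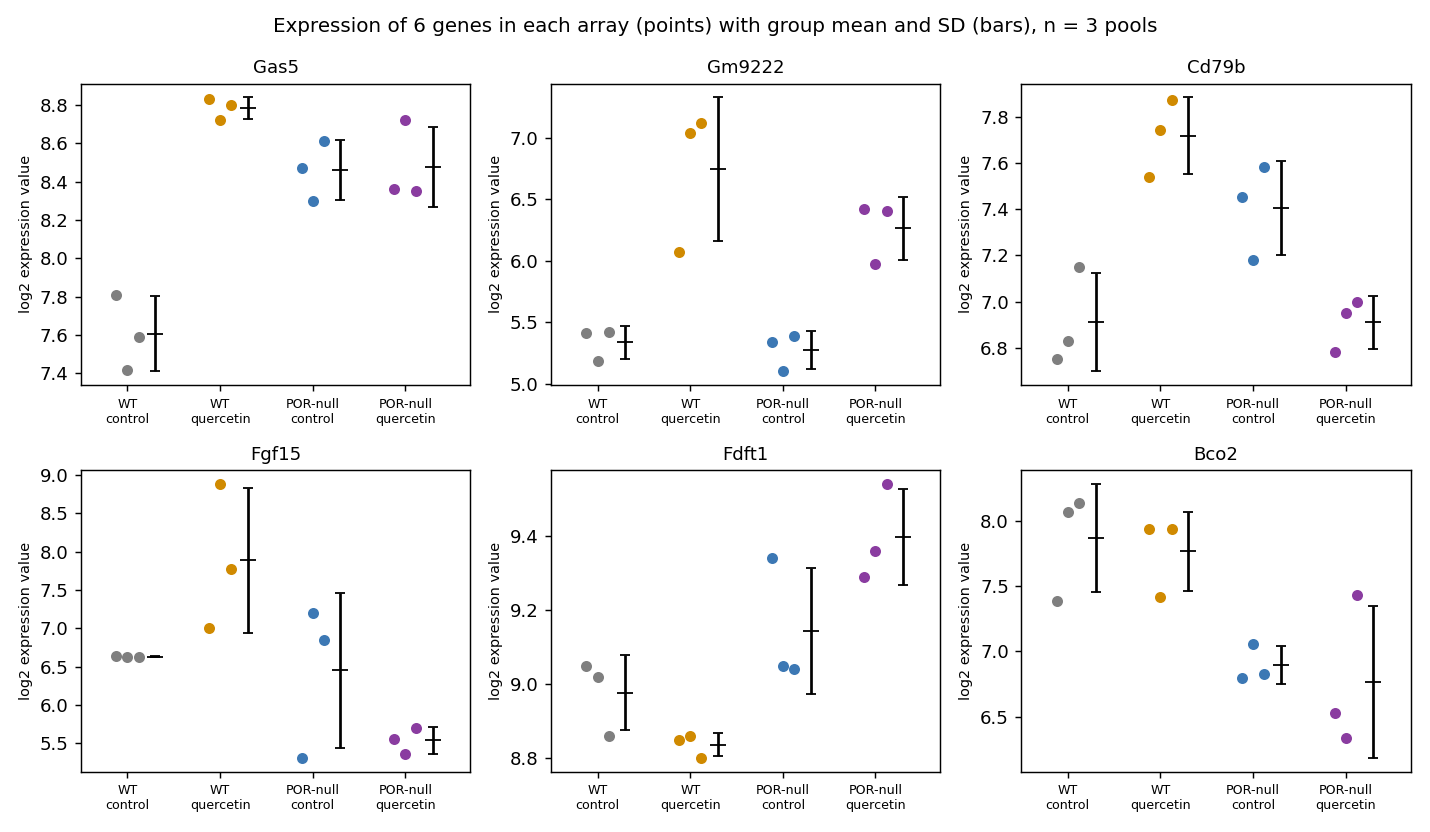
Log2 expression level of 6 genes (vertical axes, each with its own scale) on the 12 arrays by group (points, arrays; bars, group means with SD, n = 3). Gas5 had a mean of 7.61 in the wild-type control group and 8.78 in the wild-type quercetin group. In POR-null its means were 8.46 on control and 8.48 on quercetin.

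Of the fixed gene lists, B and plasma cell genes had a median difference of 0.15 on quercetin in wild type, with 12 of 16 measured members higher (camera adjusted p = 0.00105, but adjusted p = 0.578 with an estimated correlation). None of them passed over all probe sets and 1, Cd79b, passed when adjusted over the list alone. The pan-B-cell surface gene Ms4a1 (0.50 ± 0.17), Igha, the constant region of IgA (0.67 ± 0.24), and Cd79a (0.35 ± 0.12) were further members. Cell cycle genes had a median of 0.16 with 25 of 33 higher, among them the DNA replication genes Mcm6 (0.58 ± 0.16), Mcm5 (0.35 ± 0.11), Rrm2 (0.28 ± 0.10) and Pcna (0.27 ± 0.10). None passed over all probe sets or adjusted over the list alone. Camera gave this list an adjusted p of 0.00105, with adjusted p = 0.709 with an estimated correlation, and 0.541 without wild-type control replicate 2. That array lay apart and had the lowest cell cycle score of all 12 arrays (-0.31, against -0.15 to 0.12). All 9 measured genes of the ileal segment list were higher, with a median of 0.14 (camera adjusted p = 0.00634; adjusted p = 0.578 with an estimated correlation). They included Cubn, a receptor for the vitamin B12 carrier (0.31 ± 0.10), and Fgf15, the ileal hormone induced by bile acids (1.25 ± 0.44), but 0 members passed limma's test over all probe sets or adjusted over the list alone, and 2 had an unadjusted p under 0.05. On this list, too, wild-type control replicate 2 scored lowest, at -0.24 against -0.18 to 0.25. Heat shock genes had a median of -0.19, with 10 of 14 lower and none past either adjustment (camera adjusted p = 0.0419; adjusted p = 0.661 with an estimated correlation). The chaperone genes Hspa1b (-1.46 ± 0.54), Hspa1a (-0.63 ± 0.23) and Dnajb1 (-0.26 ± 0.09) and the co-chaperone gene Bag3 (-0.28 ± 0.10) had the smallest p. That call was lost without wild-type control replicate 3 (adjusted p = 0.27), wild-type quercetin replicate 1 (0.284), or POR-null quercetin replicate 1 (0.0589), 2 (0.0533) or 3 (0.0604).

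Genes that respond to foreign compounds were not called as groups in wild type. Camera gave adjusted p = 0.962 for 10 aryl hydrocarbon receptor targets, 0.63 for 22 Nrf2 antioxidant genes, 0.261 for 32 xenobiotic P450 genes, 0.527 for 20 glutathione S-transferases and 0.354 for 20 conjugation genes (glucuronidation, sulfation and methylation). Their medians were 0.02 (with a mean of -0.02), -0.05, -0.06, -0.08 and 0.01. Of 9 bile acid genes (camera adjusted p = 0.324), 1 passed when adjusted over the list alone, the bile acid receptor Nr1h4 (0.44 ± 0.12). Cyp1a1, a classic aryl hydrocarbon receptor target, differed by -0.29 ± 0.15 and Cyp2b10 by -1.19 ± 0.58, and both had their highest level of the 12 arrays in wild-type control replicate 2 (6.70 and 9.40). Adjusted over the list alone, 1 gene passed among the Nrf2 genes, Gpx2, the gastrointestinal glutathione peroxidase (-0.67 ± 0.15), and 1 among the conjugation genes, the glucuronosyltransferase Ugt2b5 (0.69 ± 0.17). Over all 22626 probe sets, limma passed 1, and 2468 had an unadjusted p under 0.05 where 1131 were expected by chance. Probe sets are not independent of each other, so this excess does not by itself show a broad response to quercetin. Apart from the averages (1683 and 1612), the other comparisons with the wild-type control arrays also had large counts (2293 and 2332). Those without these arrays had smaller ones (1505 and 1585). The number past the threshold went from 1 to 59 without wild-type control replicate 1, to 3 without POR-null control replicate 1, and to 2 without wild-type quercetin replicate 1, POR-null control replicate 3 or POR-null quercetin replicate 2. The 59 compared quercetin with wild-type control replicates 2 and 3 alone, the arrays lowest on the first component.

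In POR-null mice the same diet was compared with the control diet, which asked how the ileum responded in mice without the reductase, as far as the deletion reached it. No gene passed, and the values with the smallest p were lower on quercetin for the B cell receptor chain Cd79a (-0.66 ± 0.12), for Mylip, a ubiquitin ligase that lowers the LDL receptor (-0.40 ± 0.08), for Rprd1b (-0.38 ± 0.08), for Rbm14 (-0.34 ± 0.07) and for Pml, which forms nuclear bodies (-0.31 ± 0.06). They were higher for Cacna1b, a calcium channel subunit (0.43 ± 0.11), Adh7, an alcohol dehydrogenase (0.37 ± 0.09), Lcmt2 (0.33 ± 0.07) and the cell junction gene Cgnl1 (0.28 ± 0.07). Each had an adjusted p of 0.415 or more by limma. Rbm14 and Rprd1b each had another probe set with a difference of the opposite sign. Limma passed 0 probe sets, against 1505 at an unadjusted p under 0.05 and 1131 expected by chance.

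Among the lists in POR-null mice, all 9 measured mast cell genes were higher on quercetin, with a median of 0.15 (camera adjusted p = 0.00584; adjusted p = 0.432 with an estimated correlation). None passed over all probe sets and 1, the histamine-forming enzyme Hdc (0.26 ± 0.08), passed when adjusted over the list alone. The protease gene Mcpt1 differed by 0.46 ± 0.18. Cholesterol synthesis and uptake genes had a median of 0.13, with 17 of 19 higher, among them Lss (0.46 ± 0.14), Fdps (0.27 ± 0.11) and Fdft1 (0.25 ± 0.09), and none past either adjustment (camera adjusted p = 0.0124; adjusted p = 0.79 with an estimated correlation). Without POR-null quercetin replicate 3 this list had an adjusted p of 0.575. The remaining called lists each had an adjusted p = 0.79 with an estimated correlation and no member past either adjustment. Fatty acid oxidation genes had a median of -0.10, with 16 of 24 lower (camera adjusted p = 0.0263), and Cpt1a, which admits fatty acids to mitochondria, differed by -0.30 ± 0.14. That call was lost without POR-null control replicate 2 (0.365) or POR-null quercetin replicate 2 (0.135), with quantile normalization (0.0629) or with only probe sets above the median level (0.0728). MHC class II genes had a median of -0.19, with 8 of 11 lower (camera adjusted p = 0.0321), H2-Eb1 at -0.45 ± 0.19. It was lost without POR-null control replicate 1 (0.0505) or 2 (0.137) or POR-null quercetin replicate 1 (0.496), or with only probe sets above the median level (0.221). Heat shock genes had a median of -0.13, with 11 of 14 lower (camera adjusted p = 0.0316), Hspa1b at -1.07 ± 0.54. It was lost without POR-null control replicate 2 (0.456) or POR-null quercetin replicate 1 (0.0893) or 2 (0.065), with quantile normalization (0.0629) or with only probe sets above the median level (0.136). Of the ileal segment genes, 8 of 9 were lower, with a median of -0.13 (camera adjusted p = 0.0328), Fgf15 at -0.91 ± 0.44. It was lost without POR-null control replicate 2 (0.273) or 3 (0.35) or POR-null quercetin replicate 2 (0.0941) or 3 (0.0721), with quantile normalization (0.0629) or with only probe sets above the median level (0.136). All 7 measured Paneth cell genes were higher, with a median of 0.31 (camera adjusted p = 0.0399), the lectin gene Itln1 at 0.64 ± 0.23. It was lost without POR-null control replicate 3 (0.186) or POR-null quercetin replicate 2 (0.0941) or 3 (0.196). Camera's adjusted p was 0.867 for aryl hydrocarbon receptor targets, 0.699 for Nrf2 genes and 0.181 for xenobiotic P450 genes.

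The genotypes were next compared on the control diet, which asked how the ileum of POR-null mice differed without quercetin. Smooth muscle and stroma genes were higher in POR-null scrapings, with a median of 0.31 and 17 of 19 higher, among them the contractile genes Myl9 (1.58 ± 0.63), Myh11 (1.01 ± 0.44), Tagln (0.98 ± 0.44) and Mylk (0.36 ± 0.16). Camera gave an adjusted p of 8.24e-06, but adjusted p = 0.716 with an estimated correlation, and no member passed over all probe sets or adjusted over the list alone. The genes with the smallest p, none of which passed, were higher in POR-null for Gas5 (0.85 ± 0.12, adjusted p = 0.119), the lysosomal protease Lgmn (0.77 ± 0.13), glutamine synthetase Glul (0.67 ± 0.12), the endoplasmic reticulum protein gene Rtn4 (0.41 ± 0.08) and the monocarboxylate transporter Slc5a8 (0.39 ± 0.08). They were lower for Errfi1, an inhibitor of EGF receptor signalling (-0.87 ± 0.16), Gpx2 (-0.78 ± 0.15), the lipid phosphatase Plpp3 (-0.60 ± 0.11) and Fam3b (-0.39 ± 0.08). Limma passed 0 probe sets, with 2293 at an unadjusted p under 0.05 and 1131 expected. Gas5 passed without wild-type control replicate 1 (adjusted p = 0.0193) or POR-null quercetin replicate 2 (0.0418), Plpp3 without wild-type control replicate 1 (0.0193) and Lgmn without POR-null control replicate 1 (0.0234). Without wild-type control replicate 1 the count was 15, without POR-null control replicate 1 it was 2, and without POR-null control replicate 3 or POR-null quercetin replicate 2 it was 1. The 15 rested on wild-type control replicates 2 and 3, the arrays lowest on the first component.

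The other lists called on the control diet, beside that higher smooth muscle and stroma score in POR-null, each had an adjusted p = 0.49 with an estimated correlation. Fatty acid synthesis genes had a median of 0.14, with 13 of 15 higher and none past either adjustment (camera adjusted p = 0.0208), including the desaturase Fads2 (0.39 ± 0.12) and the elongase Elovl5 (0.29 ± 0.13), while malic enzyme Me1 was at -0.69 ± 0.31. The call was lost without wild-type control replicate 1 (0.0527), wild-type control replicate 2 (0.0813) or POR-null control replicate 3 (0.111), or with only probe sets above the median level (0.12). All 9 mast cell genes were lower, with a median of -0.16 and none past either adjustment (camera adjusted p = 0.0208); Fcer1a, a chain of the IgE receptor, differed by -0.22 ± 0.08. Without wild-type control replicate 3 the adjusted p was 0.0765. Of 20 amino acid and glucose metabolism genes, 11 were higher and 9 lower, with a median of 0.06 (camera adjusted p = 0.0352). None passed over all probe sets and 4 passed, all higher, when adjusted over the list alone: Glul, pyruvate kinase Pklr (0.47 ± 0.12) and the gluconeogenic enzymes Fbp1 (0.42 ± 0.13) and G6pc (0.46 ± 0.15). This call was lost without wild-type control replicate 1 (0.0579) or 3 (0.0765) or POR-null control replicate 2 (0.095), with quantile normalization (0.0693) or with only probe sets above the median level (0.12).

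On the quercetin diet, where the comparison asked how the genotypes differed under exposure, cholesterol synthesis genes were higher in POR-null mice. The median difference was 0.33, 17 of 19 measured members were higher, and the list had a camera adjusted p of 7.34e-11, but adjusted p = 0.404 with an estimated correlation. Over all probe sets none passed, and 11 passed, all higher, when adjusted over the list alone. Squalene synthase Fdft1 went from 8.84 ± 0.03 in wild type to 9.40 ± 0.13 in POR-null (SD, n = 3), a difference of 0.56 ± 0.09, although its other probe sets differed by 0.59, -0.01 and 0.00. Mevalonate kinase Mvk (0.46 ± 0.10), Fdps (0.45 ± 0.11) and lanosterol demethylase Cyp51 (0.46 ± 0.12), a P450 enzyme, were further members. The smooth muscle and stroma list was also higher in POR-null here, with a median of 0.22 and 19 of 19 higher, none past either adjustment (camera adjusted p = 0.000506; adjusted p = 0.873 with an estimated correlation). Tagln differed by 1.09 ± 0.44 and Des by 0.41 ± 0.17.

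**Figure D2:**
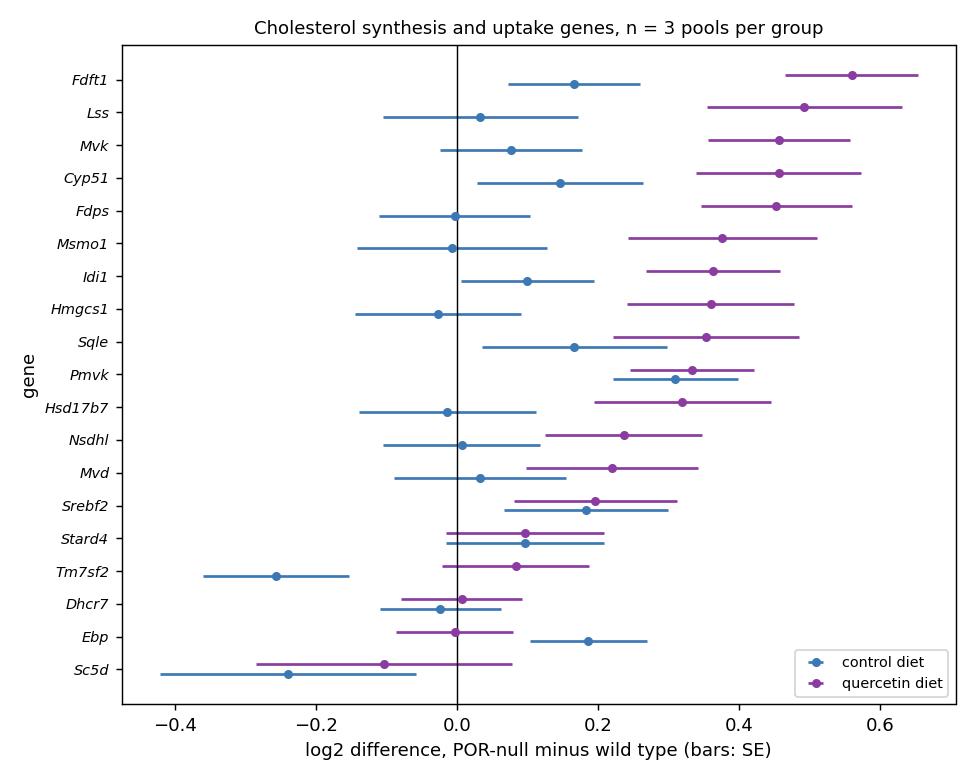
Log2 difference between POR-null and wild type of each measured cholesterol synthesis and uptake gene, on the control diet and on the quercetin diet (horizontal axis; points, differences; bars, SE; n = 3 per group). On the quercetin diet 17 of the 19 genes were above 0.

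Beside that higher smooth muscle and stroma score in POR-null, several lists were lower in POR-null on quercetin, each with an adjusted p = 0.404 with an estimated correlation. Of 58 oxidative phosphorylation genes, 52 were lower, with a median of -0.06 (camera adjusted p = 2.46e-05), for example Cox7a2 (-0.18 ± 0.07) and Atp5e (-0.18 ± 0.08). Of 24 fatty acid oxidation genes, 20 were lower, with a median of -0.11 (camera adjusted p = 0.000496), with the thiolase Acaa1b at -0.98 ± 0.33 and Acadl at -0.35 ± 0.12. Of 11 MHC class II genes, 10 were lower, with a median of -0.14 (camera adjusted p = 0.000446), such as H2-Eb1 (-0.53 ± 0.19) and the invariant chain Cd74 (-0.45 ± 0.20). None of these members passed over all probe sets or adjusted over the list alone. Of 16 B and plasma cell genes, 11 were lower, with a median of -0.03 (camera adjusted p = 2e-04). None of them passed over all probe sets and 5 passed, all lower, when adjusted over the list alone, among them Cd79b (-0.81 ± 0.13), Cd79a (-0.76 ± 0.12), Ms4a1 (-0.72 ± 0.17) and the B cell co-activator Pou2af1 (-0.61 ± 0.20). Of 9 ileal segment genes, 6 were lower, with a median of -0.09 (camera adjusted p = 0.0164). None of them passed over all probe sets and 2 passed when adjusted over the list alone: Fgf15 (-2.35 ± 0.44) and the ileal bile acid binding protein Fabp6 (-0.47 ± 0.12). The ileal call was lost without wild-type quercetin replicate 3 (0.0579) or POR-null quercetin replicate 2 (0.0555), or with only probe sets above the median level (0.0615). Other genes with small p that did not pass were, higher in POR-null, Susd2 (0.69 ± 0.14), the serine protease Prss30 (0.63 ± 0.11), the laminin chain Lamb3 (0.56 ± 0.11) and Arhgap35 (0.40 ± 0.08). Lower were Ext1, which builds heparan sulfate (-0.66 ± 0.11), C1qtnf12 (-0.55 ± 0.08) and Mylip (-0.45 ± 0.08). Limma passed 0 probe sets, with 1585 at an unadjusted p under 0.05 and 1131 expected. It passed 1 without wild-type control replicate 2 (Susd2, adjusted p = 0.0381), without wild-type control replicate 3 (Prss30, 0.0399) and without POR-null quercetin replicate 3.

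The interaction asked whether the quercetin effect differed between the genotypes, as the effect in POR-null minus that in wild type. The smallest p-values belonged to Cd79b (-1.30 ± 0.18) and Gas5 (-1.16 ± 0.17), each with an adjusted p of 0.0917, so neither passed with all arrays. Cd79b passed without wild-type control replicate 1 (0.042) or 3 (0.0344), wild-type quercetin replicate 1 (0.0482) or POR-null control replicate 2 (0.0477). Gas5 passed without wild-type control replicate 1 (0.025) or POR-null quercetin replicate 2 (0.0412), and Exosc9 without wild-type control replicate 1 (0.042). Cd79a differed by -1.01 ± 0.17, Hnrnpd by -0.85 ± 0.17, Ostf1 by -0.74 ± 0.15, the RNA exosome gene Exosc9 by -0.70 ± 0.13, Rtn4 by -0.60 ± 0.11, Mylip by -0.58 ± 0.11 and the peptide transporter Slc15a4 by -0.53 ± 0.11. Limma passed 0 probe sets, with 2332 at an unadjusted p under 0.05 and 1131 expected. The count was 9 without wild-type control replicate 1, 2 without wild-type quercetin replicate 1, and 1 without wild-type control replicate 3, POR-null control replicate 1 or 2, or POR-null quercetin replicate 2 or 3. The 9 likewise rested on wild-type control replicates 2 and 3 as the wild-type controls.

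Lists whose quercetin effect was higher in POR-null than in wild type were mast cell and cholesterol synthesis genes. All 9 mast cell genes had a positive interaction, with a median of 0.31 (camera adjusted p = 0.00237; adjusted p = 0.409 with an estimated correlation), such as Hdc (0.33 ± 0.11) and Tpsb2 (0.36 ± 0.13). The mast cell calls for quercetin in POR-null, for genotype on the control diet and here share the POR-null control arrays, so they are not separate evidence. That group had the lowest mean mast cell score, -0.10, against 0.05 and -0.04 in wild type on control and quercetin and 0.09 in POR-null on quercetin. Of the cholesterol genes 17 of 19 were positive, with a median of 0.26 (camera adjusted p = 0.00394; adjusted p = 0.614 with an estimated correlation), such as Fdps (0.46 ± 0.15) and Fdft1 (0.39 ± 0.13). This call was lost without POR-null quercetin replicate 3 (0.147). None of these members passed over all probe sets or adjusted over the list alone. Lower in POR-null were the effects on ileal segment genes, 8 of 9 negative with a median of -0.27 (camera adjusted p = 0.0018; adjusted p = 0.508 with an estimated correlation). None of them passed over all probe sets and 2, Cubn (-0.49 ± 0.14) and Fgf15 (-2.17 ± 0.62), passed when adjusted over the list alone. B and plasma cell genes had a median of -0.12, 10 of 16 negative, none past over all probe sets and 3, Cd79b, Cd79a and Ms4a1 (-0.92 ± 0.24), when adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.572 with an estimated correlation). For the remaining 3 lists no member passed either adjustment. Fatty acid oxidation genes had a median of -0.12, 19 of 24 negative, Slc25a20 at -0.51 ± 0.19 (camera adjusted p = 0.00394; adjusted p = 0.572 with an estimated correlation), and lost the call without wild-type quercetin replicate 1 (0.0631). MHC class II genes had a median of -0.22, 10 of 11 negative, H2-Eb1 at -0.69 ± 0.27 (camera adjusted p = 0.00451; adjusted p = 0.572 with an estimated correlation), and lost it without wild-type quercetin replicate 3 (0.0626) or POR-null quercetin replicate 1 (0.0727), or with only probe sets above the median level (0.0638). Cell cycle genes had a median of -0.09, 24 of 33 negative, Cks2 at -0.58 ± 0.21 (camera adjusted p = 0.0412; adjusted p = 0.922 with an estimated correlation). They lost it without wild-type control replicate 2, the array with the lowest cell cycle score (0.946), wild-type quercetin replicate 1 (0.0626) or 3 (0.177), POR-null control replicate 1 (0.351) or POR-null quercetin replicate 1 (0.61), or with only probe sets above the median level (0.188).

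**Figure D3:**
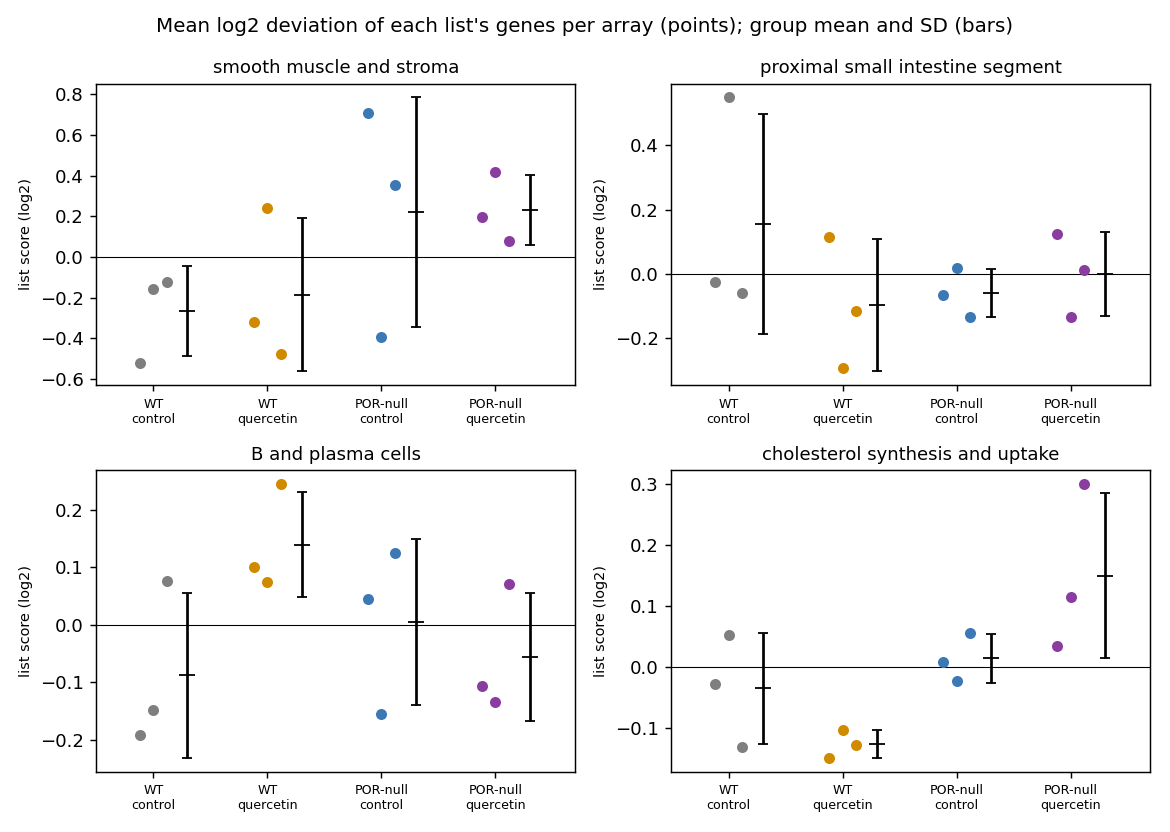
Score of 4 gene lists on the 12 arrays by group, as the mean log2 deviation of a list's genes (vertical axes; points, arrays; bars, group means with SD, n = 3). The smooth muscle and stroma score had group means of -0.27 and -0.19 in wild type and 0.22 and 0.23 in POR-null.

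Averaged over both genotypes, which set 6 quercetin arrays against 6 control arrays, heat shock genes were lower on quercetin. Their median was -0.16 with 11 of 14 lower (camera adjusted p = 0.00136; adjusted p = 0.722 with an estimated correlation). None passed over all probe sets and 4 passed, all lower, when adjusted over the list alone: Hspa1b (-1.27 ± 0.38), Hspa1a (-0.55 ± 0.16), Dnajb1 (-0.25 ± 0.06) and Bag3 (-0.22 ± 0.07). Immediate early genes had a median of -0.07, 16 of 24 lower, none past over all probe sets and 1, the stress-induced factor Atf3 (-0.54 ± 0.13), when adjusted over the list alone (camera adjusted p = 0.0214; adjusted p = 0.722 with an estimated correlation). That call was lost without wild-type control replicate 1 (0.0609), wild-type quercetin replicate 3 (0.0691) or POR-null quercetin replicate 2 (0.0721). Cell cycle genes had a median of 0.08, 24 of 33 higher and none past either adjustment (camera adjusted p = 0.0103; adjusted p = 0.954 with an estimated correlation), with Mcm6 at 0.30 ± 0.12. They lost the call without wild-type control replicate 2, the array that lay apart (0.537), wild-type quercetin replicate 3 (0.0691), POR-null control replicate 3 (0.119) or POR-null quercetin replicate 2 (0.0721) or 3 (0.0893).

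Of single genes in that average, none passed. Higher on quercetin were Gas5 (0.60 ± 0.08), the glutathione transferase Mgst1 (0.32 ± 0.08), the methyltransferase Setd6 (0.31 ± 0.06) and the transfer RNA modifying gene Osgep (0.23 ± 0.05). Lower were Grk5, a receptor kinase (-0.50 ± 0.09), Endod1 (-0.46 ± 0.09), Gda (-0.42 ± 0.07), Skil, a repressor of TGF-beta signalling (-0.30 ± 0.06), and Pml (-0.25 ± 0.05). By genotype, Gas5 went from 7.61 to 8.78 in wild type and from 8.46 to 8.48 in POR-null, Osgep from 5.59 to 6.00 and from 5.87 to 5.92, and Gda from 7.46 to 6.77 and from 6.99 to 6.83. Gda passed without POR-null control replicate 3 (adjusted p = 0.0144). Another probe set of Setd6 differed by 0.00 and another of Mgst1 by -0.07. Markers of T and intraepithelial lymphocytes (median 0.07, 18 of 24 higher; camera adjusted p = 0.0258, adjusted p = 0.954 with an estimated correlation), Paneth cells (0.21, 7 of 7; 0.0275 and adjusted p = 0.722 with an estimated correlation) and enteroendocrine cells (0.11, 15 of 18; 0.0295 and adjusted p = 0.722 with an estimated correlation) had no member past either adjustment. The lymphocyte call was lost without wild-type control replicate 2 (0.172), wild-type quercetin replicate 3 (0.246), POR-null control replicate 3 (0.119) or POR-null quercetin replicate 2 (0.0564) or 3 (0.261). The Paneth call was lost without wild-type control replicate 2 (0.172), whose Paneth score was the lowest of the 12 arrays, wild-type quercetin replicate 1 (0.152) or 3 (0.0548), POR-null control replicate 3 (0.116) or POR-null quercetin replicate 2 (0.0556) or 3 (0.0893). The enteroendocrine call was lost without wild-type control replicate 2 (0.0568) or 3 (0.128), wild-type quercetin replicate 1 (0.0857) or 3 (0.0691), POR-null control replicate 1 (0.0702) or POR-null quercetin replicate 1 (0.0568), 2 (0.0721) or 3 (0.0694), or with only probe sets above the median level (0.319). Limma passed 0 probe sets, with 1683 at an unadjusted p under 0.05 and 1131 expected. The count was 1 without wild-type quercetin replicate 1 or POR-null control replicate 3.

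Averaged over both diets, cholesterol genes were higher in POR-null, with a median of 0.19 and 16 of 19 higher (camera adjusted p = 3.25e-10; adjusted p = 0.458 with an estimated correlation). Over all probe sets none passed, and 8 passed, all higher, when adjusted over the list alone, including Fdft1 (0.36 ± 0.07), phosphomevalonate kinase Pmvk (0.32 ± 0.06), Cyp51 (0.30 ± 0.08) and Mvk (0.27 ± 0.07). Smooth muscle and stroma genes were higher too, with a median of 0.29 and 19 of 19 higher, such as Tagln (1.04 ± 0.31) and Actg2 (1.28 ± 0.46), none past either adjustment (camera adjusted p = 3.25e-10; adjusted p = 0.458 with an estimated correlation). Oxidative phosphorylation genes were lower, with a median of -0.06 and 50 of 58 lower, such as Ndufb3 (-0.20 ± 0.06) and Cox5b (-0.18 ± 0.06), none past either adjustment (camera adjusted p = 4.32e-06; adjusted p = 0.458 with an estimated correlation). Lipid absorption genes had a median of -0.08 with 15 of 19 lower and none past either adjustment, such as Apoc3 (-0.45 ± 0.16), the fatty acid transporter Cd36 (-0.33 ± 0.11) and the triglyceride synthesis genes Dgat2 (-0.22 ± 0.09) and Mogat2 (-0.13 ± 0.05). Their camera adjusted p was 0.00987, with adjusted p = 0.458 with an estimated correlation, and the call was lost without wild-type control replicate 2 (0.0902), wild-type quercetin replicate 1 (0.0866) or POR-null control replicate 1 (0.0806). No single gene passed. Those with the smallest p were higher in POR-null for Lgmn (0.59 ± 0.09), Lamb3 (0.55 ± 0.08), Prss30 (0.52 ± 0.08), Glul (0.51 ± 0.09) and the choline phosphotransferase Chpt1 (0.31 ± 0.06) (0.38 at another probe set and 0.00 ± 0.07 at a further one). They were lower for the carotenoid-cleaving enzyme Bco2 (-0.99 ± 0.18), Errfi1 (-0.63 ± 0.11), Anxa4 (-0.44 ± 0.08), C1qtnf12 (-0.39 ± 0.06) and the folate enzyme Aldh1l1 (-0.29 ± 0.05). Limma passed 0 probe sets, with 1612 at an unadjusted p under 0.05 and 1131 expected. Lamb3, Prss30 and Chpt1 passed without wild-type control replicate 2 (adjusted p = 0.0405 each), Lamb3 without wild-type quercetin replicate 2 (0.0207), Lgmn without POR-null control replicate 1 (0.0216), C1qtnf12 without POR-null control replicate 3 (0.0344) and Bco2 without POR-null quercetin replicate 3 (0.0453). The count was 6 without wild-type control replicate 2, 2 without POR-null control replicate 1 or 3, and 1 without wild-type quercetin replicate 2 or POR-null quercetin replicate 3.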

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

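Every test in this part was chosen after the result it concerns was seen, apart from the interaction tests of the gene lists, which were fixed before.

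A difference in quercetin response between the genotypes was called by camera at the preset correlation for 7 lists: ileal segment (adjusted p = 0.0018), mast cell (0.00237), B and plasma cell (0.00237), cholesterol (0.00394), fatty acid oxidation (0.00394), MHC class II (0.00451) and cell cycle genes (0.0412). None held with an estimated correlation, where the smallest adjusted p was 0.409, or by fry, where it was 0.0884. Of 100 splits of the 12 arrays, the real one included, 45 gave at least 7 called lists, with up to 13 in another split, so chance was not excluded. For probe sets the real count was 0 and the highest other 6; since all 100 splits reach a count of 0, that comparison decides nothing. Leaving out 1 array ended the cholesterol call (0.147 without POR-null quercetin replicate 3), the fatty acid oxidation call (0.0631 without wild-type quercetin replicate 1) and the MHC class II call (0.0626 without wild-type quercetin replicate 3, 0.0727 without POR-null quercetin replicate 1). The cell cycle call ended without wild-type control replicate 2 (0.946), wild-type quercetin replicate 1 (0.0626) or 3 (0.177), POR-null control replicate 1 (0.351) or POR-null quercetin replicate 1 (0.61).

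Wild-type control replicate 2 lay apart from the other 11 arrays. Degraded RNA is argued against by the actin control, whose 3' minus 5' difference was 0.85, within 0.60 to 1.03 in the others. More proximal intestine in that pool stays open: its proximal score was 0.42 above the highest other array, and its ileal score the lowest of all 12. A lower share of crypt tissue may also be involved, since it had the lowest score on 3 of 3 crypt lists (Paneth -0.63, cell cycle -0.31, stem cell -0.23). These explanations do not exclude each other, and no biological explanation was tested for a single pool.

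Cholesterol genes were higher in POR-null than wild-type ileum on quercetin, with a median of 0.33. Muscle and stroma carried over in the scraping is argued against as the whole cause by the median alone, which was 0.31 with each array's stroma score in the model. Camera's adjusted p was then 5.28e-10 at the preset correlation (without the score, 7.34e-11, but adjusted p = 0.404 with an estimated correlation). No estimated correlation was run with the score in the model, so the 5.28e-10 decides nothing. Weaker bile acid signalling in POR-null ileum stays open: on quercetin 5 of 5 chosen bile acid responsive genes had the sign it predicts, namely Fgf15 (-2.35 ± 0.44), Fabp6 (-0.47 ± 0.12), Slc51a (-0.31 ± 0.13), Nr0b2 (-0.08 ± 0.13) and the uptake transporter Slc10a2 (0.77 ± 0.50). All of these but Nr0b2 are also on the ileal segment list, so the signs are not evidence separate from that list's call. The signs do not decide this explanation. On the control diet, where camera did not call the cholesterol list (adjusted p = 0.128), 4 of 5 had that sign too. Each did so by less than 2 SE (Fgf15 -0.18 ± 0.44, Fabp6 -0.20 ± 0.12, Nr0b2 -0.21 ± 0.13, Slc10a2 0.68 ± 0.50). That count is itself unsure, as the Fgf15 sign rested on POR-null control replicate 1 (5.31, with 7.20 and 6.85 in replicates 2 and 3, against 6.63 to 6.64 in wild type). Wild-type control replicate 2 also had the lowest Slc10a2 level of the 12 arrays (5.22, group mean 6.20). On quercetin, camera did not call the whole list of 9 bile acid genes (adjusted p = 0.137). A need of Cyp51 and Sqle for POR was not tested, since Por is not analysed here and the labels do not say whether the deletion reached the ileum.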

How the results depend on the processing

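All alternatives here were fixed before the data were examined. None of 181 gene values or 39 list calls changed sign. These values and lists were picked by small p on the same arrays, so kept signs were likely and do not show robustness. Only 1 of the gene values passed in the main fit, so most that kept their side of the threshold had not passed it. Of 3680 gene comparisons with an alternative, 3617 kept their side of the threshold, 62 came to pass and 1 no longer passed (Gas5 in wild type as the mean of its probe sets, adjusted p = 0.0561; from 0.000488 to 0.035 otherwise). Of 663 list comparisons, 501 kept the call and 162 lost it. With an estimated correlation or by fry, 0 lists were called in any contrast. Causes were not tested except where fewer arrays or probe sets were used.

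Leaving out 1 array in turn, the probe sets past the threshold ranged from 1 to 59 for quercetin in wild type (1 with all arrays), 0 in POR-null, 0 to 15 for genotype on the control diet, 0 to 1 on quercetin, 0 to 9 for the interaction, 0 to 1 for the average quercetin effect and 0 to 6 for the average genotype effect (0 with all arrays). The 59, 15 and 9 came without wild-type control replicate 1, which kept the wild-type controls lowest on the first component. Lists called ranged from 3 to 9 for quercetin in wild type (4 with all arrays; 9 without wild-type control replicate 1, 7 without its replicate 2 or wild-type quercetin replicate 2) and 3 to 8 in POR-null (7 with all; 3 without POR-null quercetin replicate 2). For genotype on the control diet they ranged from 4 to 7 (4 with all; 7 without POR-null control replicate 1). The average quercetin effect ranged from 1 to 7 (6 with all; 1, 2 and 3 without POR-null quercetin replicate 2, wild-type quercetin replicate 3 and POR-null quercetin replicate 3), and the average genotype effect from 4 to 7 (4 with all; 7 without wild-type quercetin replicate 2).

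Quercetin in wild type gave 7 probe sets without the dimmest ones or with trend and robust, 2 with only the arrays compared and 13 at a threshold of 0.10. By gene mean, limma passed 0 of 12393 genes, with 1375 at an unadjusted p under 0.05. That count is of genes and cannot be set against counts of the 22626 probe sets. With trend and robust, genotype gave 1 on the control diet and 5 on quercetin, the interaction 2, average quercetin 1 and average genotype 4. Named genes that passed with trend and robust included Cd79b, Hnrnpd and Gda for quercetin in wild type (adjusted p = 0.0221, and 0.0459 without the dimmest probe sets), Gas5 for genotype on the control diet (0.0387), and Cd79b (0.0265) and Gas5 (0.0319) for the interaction. With only the arrays compared, genotype on quercetin gave 2. At 0.10 the interaction and both averages gave 2. Average quercetin gave 2 with centring and 1 without the dimmest probe sets or with array weights, and average genotype 4 with array weights. Lists called were 7 with quantile normalization and 8 with only probe sets above the median level for quercetin in wild type, 4 and 3 in POR-null, and 7 with only probe sets above the median level for average genotype.

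Replicate numbers name different pools. To see whether same-numbered arrays deviated together, each probe set's group mean was subtracted and the remainders were correlated between arrays of different groups. Same-numbered pairs had a median correlation of 0.016 (-0.179 to 0.162, 3 of 18 above 0.1), and differently numbered pairs 0.001. With the number as a block, probe sets past the threshold were 5 for quercetin in wild type, 2 for genotype on quercetin, 3 for the interaction and 2 for average genotype, and 39 of 39 list calls remained. A pseudocount was not varied, since the values are log2. Signal over background per array is not analysed here.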

Other observations

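In the tests of Gas5 and ribosomal protein genes, the ribosomal list and the shared control arrays were chosen after the data were seen, as were the splits and the correlations within groups; the tests of abundant genes, of single arrays and of small nucleolar RNA hosts were set before their results, except that the value of the host gene Snhg1 had been seen.

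In wild-type mice on quercetin, ribosomal protein genes, which like Gas5 carry the pyrimidine tract of growth-regulated messages, were higher together, with a median of 0.27 and 41 of 42 higher. Rps19 differed by 0.48 ± 0.10, Rps18 by 0.47 ± 0.12 and Rpl8 by 0.29 ± 0.07. None passed over all probe sets with all arrays and 34 passed when adjusted over the list alone. Without wild-type control replicate 1, Rps18 (0.61, limma adjusted p = 0.0434) and Rps19 (0.58, 0.0486) passed over all probe sets, as did probe sets of Rpl27 and Rpl11. Camera gave 3.29e-30 adjusted over the 2 lists added after the data were seen, and adjusted p = 0.0286 with an estimated correlation, but adjusted p = 0.532 with an estimated correlation over all 41 lists. Without wild-type quercetin replicate 2 or 3 it was 0.0536 or 0.0537 over the 2 lists. The scores were -0.02, -0.30 and -0.13 on wild-type control arrays 1 to 3, and 0.06 to 0.15 on the quercetin arrays. Cell cycle genes (median 0.16, 25 of 33 higher; adjusted p = 0.709 with an estimated correlation) and B and plasma cell genes (median 0.15, 12 of 16 higher; adjusted p = 0.578 with an estimated correlation) were higher in the same comparison. Cell cycle scores on those control arrays, 0.11, -0.31 and -0.01, were likewise highest in replicate 1 and lowest in replicate 2. In POR-null mice the median on quercetin was 0.02. Against wild type, POR-null arrays had a median of 0.16 on the control diet, 40 of 42 higher (adjusted p = 0.144 with an estimated correlation), and -0.08 on quercetin, 38 of 42 lower (adjusted p = 0.466 with an estimated correlation). The scores of POR-null control arrays 1 to 3 were 0.01, -0.03 and 0.05. Wild-type control replicates 2 and 3 were thus low against POR-null controls too, while replicate 1 lay within their range. The interaction had a median of -0.25, 41 of 42 lower (adjusted p = 0.111 with an estimated correlation).

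A shift of all abundant genes is argued against, as 446 other genes of the same level had a median of -0.0233. A single control array as the whole source is argued against by the lowest median without 1 of them, 0.19 (without replicate 2), where all arrays gave 0.27. Replicate 2, the array that lay apart, had the lowest score (-0.30), and part of the difference may come from it. A rise shared by ribosomal protein genes may include Gas5, with the median of 0.27. A rise shared by host genes of small nucleolar RNAs was predicted to show as a camera call, which was not made (6 genes, median 0.0417, 4 higher, adjusted p = 0.125 over the 2 lists); it is left open because the members ran from -0.11 to 0.42, wider than the median, a reading chosen after the value was seen. No biological explanation was tested beyond diet and genotype.

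Gm9222, a predicted gene, was 1.20 ± 0.15 higher over both genotypes (limma adjusted p = 0.0512, and 5.51e-05 without wild-type quercetin replicate 1), with all 6 quercetin arrays above all 6 control arrays. The difference was 1.41 ± 0.22 in wild type (limma adjusted p = 0.0577, 0.0486 without wild-type control replicate 1 and 0.000342 without wild-type quercetin replicate 1) and 0.99 ± 0.22 in POR-null. Its probe set is of a type that may bind other transcripts, and none of these values tests that.

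The quercetin effect in wild type and the genotype effect on the control diet share their control arrays. Across 12393 genes, which are not independent replicates, they correlated with r = 0.643 and a covariance of 0.0135. In 100 simulations without effects the medians were 0.502 and 0.00551 and the highest covariance 0.00629, so sharing the arrays gave a likeness by itself. How much of the real likeness comes from the shared arrays cannot be told. The simulated noise was independent between genes and had the same SD in each group. The real wild-type control group had a median SD of 0.107, against 0.0896 to 0.0929 in the other groups, so the simulated covariance may be too low. Without control replicate 1, 2 or 3 the correlation was 0.756, 0.62 or 0.698 and the covariance 0.0233, 0.0122 or 0.0174. These values share 2 control arrays and the simulations 3, so they cannot be set against the simulated ones. Effects that share no arrays correlated with r = -0.0874 (quercetin in either genotype) and -0.0156 (genotype on either diet).

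For groups of 3 the 10 splits are too few for a share under 0.05. Real and highest other counts of probe sets were 1 and 0 for quercetin in wild type, 0 and 0 in POR-null, 0 and 6 for genotype on the control diet and 0 and 0 on quercetin; of lists they were 4 and 11, 7 and 9, 4 and 12, and 7 and 11. Counts as large came from 9, 6, 8 and 4 of the 10 splits for lists, and from 1, 10, 10 and 10 for probe sets, where a real count of 0 is reached by every split. The real grouping is among the splits counted, and the 1 for probe sets in wild type is that grouping itself. For the averages chance was not excluded: 56 of 100 splits, the real one included, gave as many lists as the 6 for quercetin (highest other 16) and 84 as many as the 4 for genotype (17). For probe sets the real counts were 0 (highest others 6 and 4), which all 100 splits reach, so that comparison decides nothing.

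The P450 genes Cyp2b10 (5.84 to 9.40), Cyp3a11 (8.86 to 11.07) and Cyp1a1 (5.75 to 6.70) ranged widely over the 12 arrays, each highest in wild-type control replicate 2, where the Paneth cell gene Lyz1 had its lowest level (10.90). Within groups, B and plasma cell genes correlated with a median of 0.303, against 0.0127 for random sets of the same size, smooth muscle and stroma genes with 0.699 and cholesterol genes with 0.272. Mast cell genes correlated with 0.041, against 0.0332 for random sets (95th percentile 0.203).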
